A study of Escherichia coli BW25113 with 44 samples.

How the data were processed

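The deposited values are raw counts per gene for each of 44 libraries, 1 count column per library. Per the labels' protocols, cells were grown from an overnight LB culture that was washed and moved to M63B1 medium, collected in log phase, and lysed with lysozyme and proteinase K, and RNA was cleaned with beads. Per the submitters' processing notes, cutadapt 2.10 and Bowtie2 2.4.1 were used before counting. The counting program, the genome build and annotation, and any use of molecular identifiers are not given in the sources used here.

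Of 4531 gene identifiers, 4526 matched the RefSeq annotation of strain MG1655 (ASM584v2), which was used only for gene names, gene types and neighbours, and 5 did not. The 22 rRNA genes were left out of library sizes and tests, which left 4509 genes, and their share of counts is reported for each group. CPM, counts scaled to a common total, were computed from the non-rRNA total.

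The groups, comparisons, gene lists, main tests and most alternatives were chosen before the data were examined. The list tests at 1 ng, total count scaling at each input, the use of 1 ng as the reference, the depth without rRNA and the comparisons without tRNA and other non-coding genes were chosen after.

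Groups of 2 were compared with edgeR 4.0.16 in R 4.3.3, using TMM scaling, a quasi-likelihood F test and edgeR's filter on low counts with a minimum count of 10, and an adjusted p (Benjamini-Hochberg) under 0.05 was the threshold. DESeq2 1.42.0 and limma 3.58.1 (voom) were run as alternatives. Each of 42 gene lists written from general knowledge was tested, where at least 4 members were measured, with camera at a preset correlation between genes of 0.01 and again with an estimated correlation. Counts of list members are given with p adjusted over all genes, and again over the list alone.

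Pairs of single libraries were compared by log2 ratios after TMM scaling for genes with at least 50 counts in either library, with no p-value. The median ratio of a list was placed among 10000 random lists matched on expression, and counting intervals are exact binomial intervals at 95%. A gene with 0 counts in 1 group was given only a limit on its ratio, with a floor of 3 counts per library. Correlations are on log2 (CPM + 1). Detected genes are expected numbers with at least 5 counts after thinning to the smallest total of 16427 counts.

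Genes named in the comparisons of 2 libraries against 2 had an adjusted p under 0.05, a mean of at least 50 counts, and both libraries of one group above both of the other, and the largest changes were taken in each direction. For single libraries the 8 highest and 8 lowest ratios were taken among genes with at least 100 counts in either. The 2 members with the smallest p were named for each list, a rule that was extended to 1 ng after the data were seen.

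Each step was first run on simulated counts with 200 genes changed by known amounts. Of 4-fold changes 69% were recovered at 1 ng, over 3487 genes, 41% at 100 pg, over 3151 genes, 0% at 10 pg, over 2984 genes, 1% at 1 pg, over 2972 genes, and 0% at 100 fg, over 2973 genes. For pos against neg 0% were recovered over 3668 genes by the fit without the replicate number. With it in the fit and in the simulated counts 75% were recovered. For 1 RT primer against 23 the value was 74% over 2711 genes. Of 2-fold changes 19% were recovered at 1 ng, 7% at 100 pg and 18% for the RT primers. Both RT primer values come from changes placed in 1 library, with p adjusted over fewer tests than the 65064 of the data. Recovery with the other primers, whose libraries differed in depth, was not simulated.

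Replicates differed by more than sampling noise in every group of 2, with chi-square values per degree of freedom from 10.0 at 100 pg to 113.8 at 100 fg, so each library was counted once.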

Results

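RNA-seq read counts were obtained from 44 libraries of Escherichia coli BW25113, a K-12 laboratory strain, which the labels describe as grown in M63B1 medium to log phase. The series tests miniBac-seq, a library protocol for small amounts of bacterial RNA. By the labels, commercial rRNA depletion, customized rRNA depletion, miniBac-seq and TruSeq, a commercial library kit, had 1 library each. Total RNA inputs in 6 amounts from 5 ng down to 100 fg, each step below 1 ng being 10-fold, had 2 libraries each, and 24 libraries carried 1 reverse-transcription (RT) primer each. The last 4 libraries were labelled neg and pos, with 2 each, and the labels give RT primer 24 for all 4 and do not say what the words stand for. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these libraries only, which may be technical.

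Total counts ranged from 16427 in 100 fg library 1 to 8153770 in the TruSeq library. The commercial and customized depletion libraries held 3845090 and 4357368 counts, and the miniBac-seq library set beside TruSeq held 6355497. Totals lay between 2190276 and 3059495 at 5 ng, 1598780 and 1991174 at 1 ng, 120870 and 193706 at 100 pg, 30049 and 47053 at 10 pg, 19324 and 19488 at 1 pg, and 16427 and 26494 at 100 fg. The RT primer libraries held 594983 to 2756378 counts, the neg libraries 1560822 to 2065382 and the pos libraries 1176448 to 2022378. Counts of mRNA and other non-rRNA genes were scaled to CPM of the non-rRNA total. Confidence intervals and limits for zero counts cover counting error only, because no molecular identifiers are known for these libraries.

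The most abundant transcripts differed between the sets of libraries. Glutamate-dependent acid resistance genes (gadA, gadB, gadC) and dps, which encodes the DNA-protecting protein of starved cells, were among the 5 highest genes in the customized depletion library, at 1 ng, at 100 pg and at 10 pg. The same gad genes with dps and hdeA, a periplasmic acid chaperone gene, led the commercial depletion library, and hdeB, its neighbour, was the last of the 5 in the customized one. Tryptophanase (tnaA, b3708) led at 5 ng with 70747 ± 8577 CPM (SD, n = 2), ahead of aceA, gatC, csrB and ompC. Outer membrane proteins and elongation factors (ompA, ompC, tufA, fusA) were at the top of the miniBac-seq, TruSeq, neg and pos libraries, with methionine synthase (metE) in the first 2 sets and the galactitol gene gatZ in the last 2. The RT primer libraries were led by gapA, tufA, ompC, fusA and tdcE. The sensor kinase gene barA, mrcA, rho, amtB and yfhL led at 1 pg and at 100 fg, and barA was also second at 10 pg. Of the genes deleted in BW25113, araB, araA, araD, rhaB, rhaA and rhaD had at most 11 counts in any of the 44 libraries, and lacZ also had at most 11. hsdR, which was listed with them but is known in this strain as a mutant allele and not a deletion, reached 1228 counts and had counts in all but 3 libraries. Reads of gadA and gadB, of tufA, and of most tRNA genes can fall on near-identical copies, so the split between copies is uncertain.

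The customized depletion library was compared with the commercial one to see whether the depletion method alters transcript levels. ssrA (b2621), the tmRNA that frees stalled ribosomes, had 64159 counts after commercial and 18 after customized depletion, a 3860-fold difference (exact 95% counting interval 2510 to 6694). In the other direction, csrB (b4408), a small RNA that sequesters the carbon storage regulator CsrA, was 12.5-fold higher after customized depletion, with 18307 against 1313 counts. The stress genes yjbJ and pspE were 4.75-fold and 5.11-fold higher, and fumD, mntR, ydiZ, yraR and yaiA were 3.82-fold to 5.19-fold higher. The other lower genes differed less, and ybaA, ogt, rfbC, uof, gudD, tff and wecF were 2.04-fold to 2.61-fold lower.

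Small RNAs had a median log2 ratio of 0.82 over 6 genes, at percentile 99.95 of random lists matched on expression, with 3 at least 2-fold higher and ssrA lower. Ribosome hibernation factors, which silence ribosomes in slow growth, had a median of 0.73 over 4 genes (percentile 99.62), and raiA and sra were 2.24-fold and 2.23-fold higher. Nucleoid proteins had a median of 0.40 over 6 genes (percentile 98.26), with hns 1.43-fold and ihfA 1.75-fold higher. In all, 96 of 2819 genes with at least 50 counts in either library were at least 2-fold apart, 82 of them higher after customized depletion, where counting error alone gave a mean of 0.15. Pearson's r across the 4509 genes, which are not independent replicates, was 0.985. rRNA made up 0.0161% of counts after commercial and 0.00186% after customized depletion. With 1 library per method the difference has no replicate check, and across 1360 genes the ratios correlated with the difference between RT primers 2 and 1 (r = 0.610), the highest of all ordered pairs of primers.

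The miniBac-seq library was compared with the TruSeq library for overall performance. Small stable RNAs were lower with miniBac-seq, where ssrA had 19 counts against 95328, ryhB, the iron-responsive small RNA, 3 against 1989, and glmZ 3 against 549. ssrA was also at 16689 CPM after commercial and 4.13 CPM after customized depletion. For ssrA the library protocol therefore cannot be told apart from the rRNA depletion used. The abundant lipoprotein gene lpp (b1677) had 134 counts against 29366, a 163-fold difference (exact 95% counting interval 138 to 195). rmf, a ribosome hibernation factor gene, was 78.2-fold lower, while yncL and argU had 1 count each and asnU had 0, which puts asnU at least 33.1-fold lower. The genes with the highest ratios were yabQ, at least 52.6-fold higher with 117 counts against 0, and metU, glnU, yceK and leuT, with 335, 148, 177 and 345 counts against 1, 5, 15 and 51. They were followed by rspB, moaD and yahO, which were 6.39-fold to 7.02-fold higher.

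Of 14 small RNAs 13 were at least 2-fold lower with miniBac-seq, with a median log2 ratio of -3.63 that lay below all 10000 random lists. Transfer RNAs had 23 members lower and 6 higher of 43 (median -1.28), with lysT 1.49-fold lower and thrT 2.03-fold higher. Arginine biosynthesis genes had 9 of 12 members lower (median -1.44, carB 2.63-fold), and methionine biosynthesis genes 4 of 10 (median -0.99, metK 2.82-fold). Ribosome hibernation factors had 3 of 4 lower, sra by 8.90-fold and raiA by 2.48-fold. Acid resistance genes had 6 of 11 members higher (median 1.04, hdeB 2.68-fold), and phage shock genes 3 of 5 (percentile 99.6, pspA 2.76-fold). Medians of toxin-antitoxin, fimbrial and SOS genes were above the central 95% of random lists by smaller margins, with relE 3.21-fold, csgD 1.88-fold and recA 1.61-fold higher. Medians of iron acquisition, purine, TCA cycle, pyrimidine and nucleoid protein genes lay below it, at -0.23, -0.36, -0.44, -0.67 and -0.66, with pyrB 2.25-fold and hupA 1.58-fold lower. At least 2-fold apart were 702 of 3306 genes, 312 higher and 390 lower, where counting error alone gave a mean of 0.65, and Pearson's r across genes was 0.948. As 1 library stood for each protocol, these values describe 2 libraries and carry no replicate check.

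**Figure D1:**
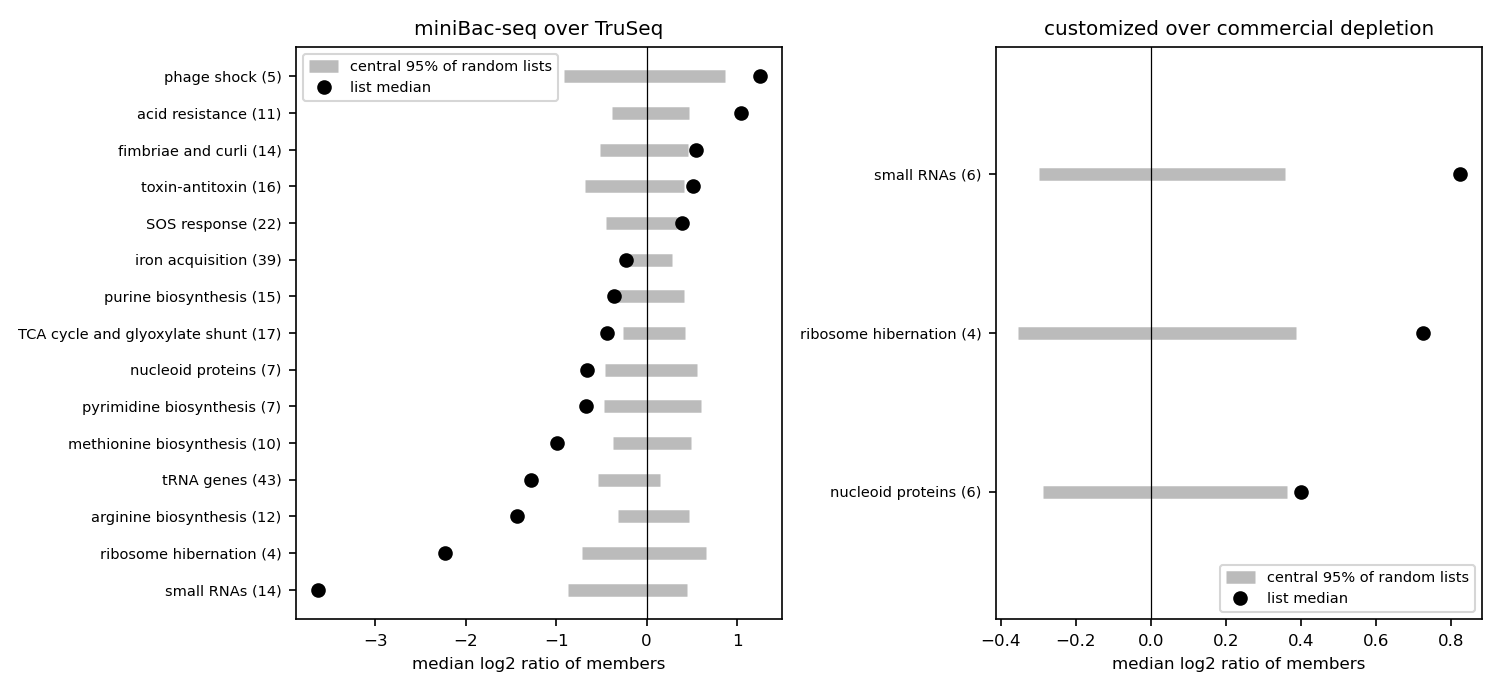
Median log2 ratio of the members of each gene list (points, with the number of members in brackets) and the central 95% of 10000 random lists matched on expression (grey bars), for lists outside the central 95%. Small RNAs lie at -3.63 for miniBac-seq over TruSeq and at 0.82 for customized over commercial depletion.

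The 24 RT primer libraries address whether the primer used for reverse transcription alters quantification. Single transcripts stood far above their usual level with 1 primer. hisR (b3797), the histidine tRNA, reached 6040 CPM with primer 3 against a median of 127 CPM with the others, and ilvE (b3770), the branched-chain aminotransferase gene, reached 1770 CPM with primer 8 against 62.5. The fitted log2 differences were 5.39 (SE 0.37, adjusted p = 3.5e-11) for hisR and 4.78 (SE 0.24, adjusted p = 5.6e-15) for ilvE in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. torT was 46.8-fold higher with primer 8 and metT 24.6-fold higher with primer 21, and both were named after their values were seen.

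The 8 genes with the largest spread among 1523 genes with a mean of at least 100 counts were hisR, ybcH, rlpA, ilvE, yfcZ, metW, gcvB and yqgB. Their SD of log2 CPM over 24 libraries ran from 0.87 to 1.37, beside a median of 0.31 over the 1523 genes. The small RNA gcvB averaged 2286 ± 2082 CPM (SD, n = 24) and peaked at 9065 CPM with primer 18, and the lipoprotein gene rlpA averaged 1731 ± 1487 CPM and peaked at 6656 CPM with primer 21. By list, the median SD of log2 CPM was 0.57 for 5 small RNAs, 0.49 for 29 tRNA genes and 0.39 for 54 ribosomal protein genes. It was 0.21 for 22 aminoacyl-tRNA synthetase genes and 0.21 for 11 DNA replication genes. A call in any primer was made for 9 ribosomal protein genes, 7 tRNA genes, 4 of 9 ATP synthase genes and 0 small RNAs.

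With each primer tested against the other 23, 247 of 65064 tests passed, 231 higher and 16 lower, and they fell on 247 different genes. Calls per primer ranged from 0 with primer 9 (99 genes at an unadjusted p under 0.05) to 52 with primer 21, and primers 12 and 8 had 47 and 19. The primer 21 library had the fewest counts of the 24 (594983) and the lowest mean r with the others (0.927). Its primer therefore cannot be told apart from the library. limma voom made 376 calls in all. The common biological coefficient of variation over the 24 libraries was 27.8% (jackknife SE 1.27%), beside 20.3% for the 5 ng pair and 24.4% for the 1 ng pair, and the median pairwise r across genes was 0.952 (0.909 to 0.971). The 2 pairs are no measure of spread at 1 fixed primer, as their RT primers are not given. Their differences correlated best with that between RT primers 2 and 1 (r = 0.637 and 0.575), and their depths also differed from those of the 24. Each primer had 1 library, which is assumed to vary like the others.

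**Figure D2:**
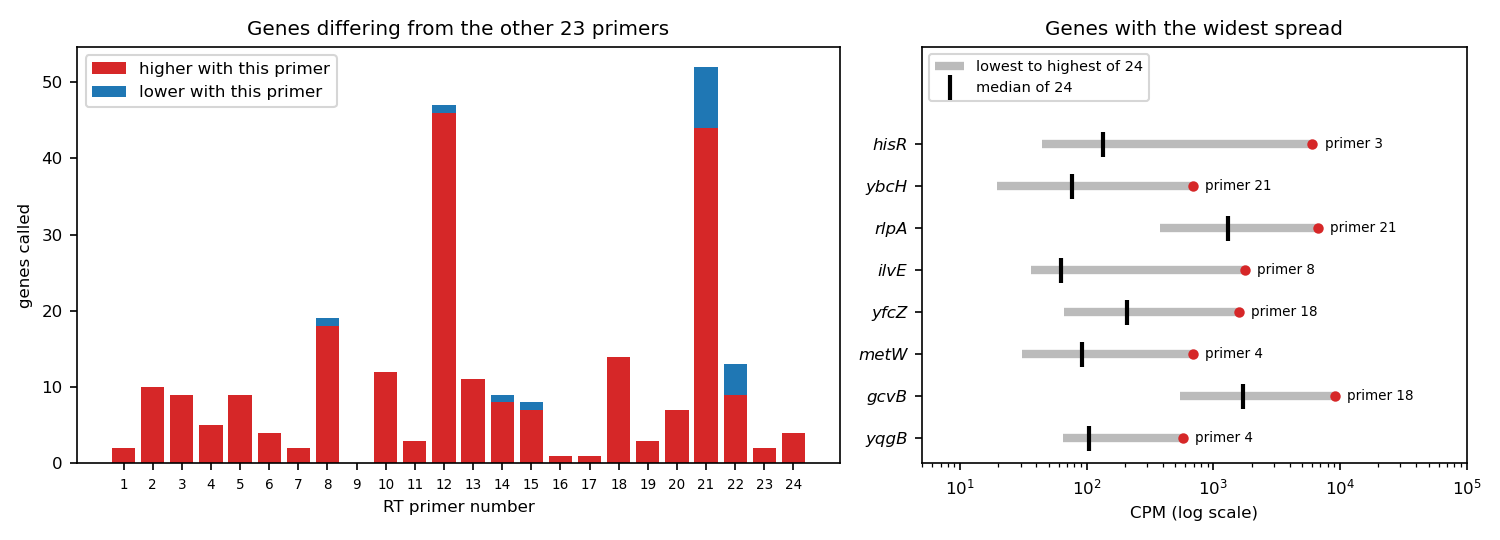
Left, number of genes called with each RT primer against the other 23 (red higher, blue lower). Right, range of CPM over 24 libraries for the 8 genes with the largest spread (grey, log scale), with the median and the primer of the highest value, such as 6040 CPM for hisR with primer 3.

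The input series asks how little RNA still gives a usable profile. At 100 pg the acid resistance transcripts and dps stood near the levels of 1 ng, with gadB at 27629 ± 1493 CPM (SD, n = 2) against 28254 ± 1662, while at 100 fg gadB was at 837 CPM on average. Thinned to 16427 counts, libraries held at least 5 counts for 680.5 ± 2.87 genes at 5 ng, 621.6 ± 7.79 at 1 ng, 609.8 ± 11.5 at 100 pg, 457.6 ± 2.42 at 10 pg, 165.8 ± 7.67 at 1 pg and 96.8 ± 27.2 at 100 fg (SD, n = 2). Of the 49 genes above 3000 CPM at 1 ng, 98.0% had counts in both libraries at 1 pg and 42.9% at 100 fg, and of the 631 genes between 100 and 300 CPM, 99.2% had counts in both libraries at 100 pg, 32.5% at 10 pg and 4.28% at 100 fg.

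The share of rRNA counts was 0.183% ± 0.0671 at 5 ng, 0.856% ± 0.152 at 1 ng, 7.47% ± 1.67 at 100 pg, 42.2% ± 3.97 at 10 pg, 69.2% ± 7.84 at 1 pg and 75.6% ± 1.16 at 100 fg (SD, n = 2). The rRNA counts themselves stayed between 10458 and 19822 in every library from 1 ng to 100 fg. Over the same inputs the non-rRNA counts went from 1583385 and 1976274 at 1 ng to 3868 and 6672 at 100 fg. The rise in share from 1 ng down thus followed the fall of the other counts. Pearson's r across genes between the 2 libraries of an input was 0.980 at 5 ng and 0.951, 0.777, 0.512, 0.293 and 0.196 at the lower inputs in turn. Correlation with the 5 ng libraries was 0.90, 0.841, 0.643, 0.442 and 0.254. With the 1 ng libraries as the reference it was 0.915, 0.711, 0.484 and 0.263 from 100 pg down. At a depth set by the smallest total without rRNA, 3868 counts, the number of detected genes was 179 at 5 ng, 182 at 1 ng, 184 at 100 pg, 192 at 10 pg, 129 at 1 pg and 94.6 at 100 fg.

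**Figure D3:**
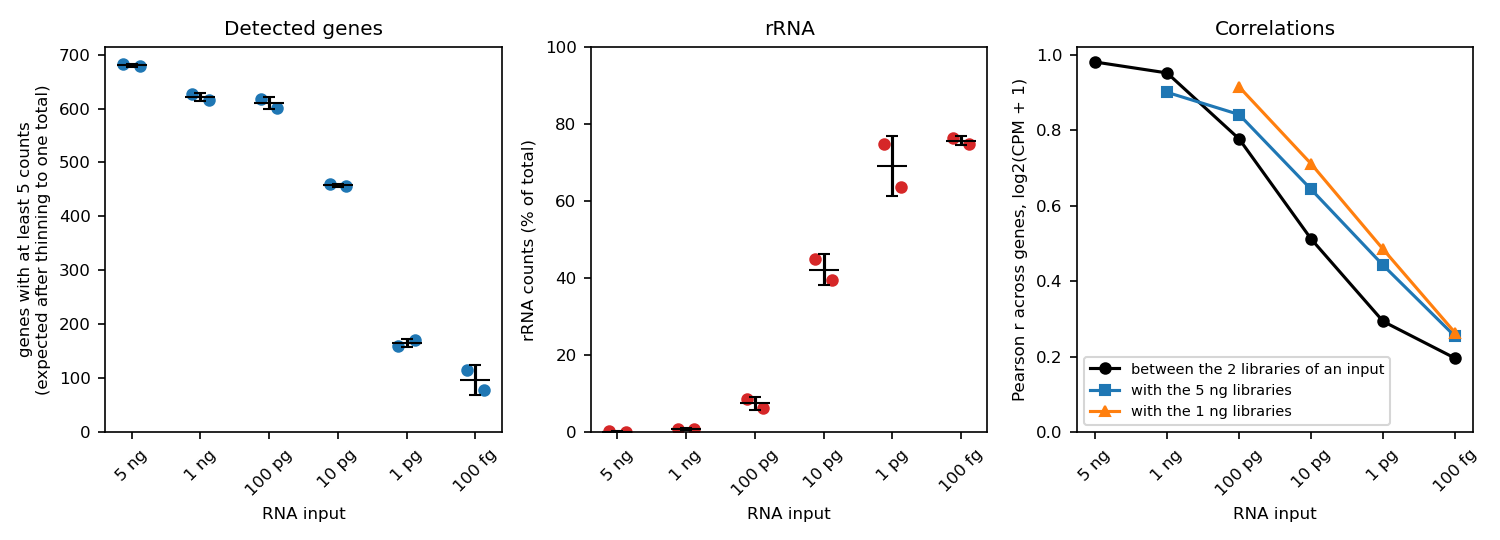
Genes with at least 5 counts after thinning to 16427 counts, percent of rRNA counts (points are libraries, bars mean and SD, n = 2) and Pearson's r across genes, by RNA input. The thinned totals include rRNA, so detected genes go from 680.5 at 5 ng to 96.8 at 100 fg partly because rRNA takes 75.6% there, and at 3868 non-rRNA counts they number 179 at 5 ng and 192 at 10 pg.

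Against 5 ng, the 1 ng libraries differed in many gene groups. The hybrid cluster protein gene hcp (b0873), induced by nitric oxide, and its reductase hcr (b0872) rose by log2 9.89 (SE 0.49) and 8.37 (SE 0.39), from 7.13 ± 5.45 to 5534 ± 224 CPM and from 5.50 ± 1.95 to 1617 ± 417 CPM (SD, n = 2). bssR, a regulator of biofilm formation, rose by 7.12 and yjiH by 6.63. Aspartate carbamoyltransferase (pyrB, b4245), the first enzyme of pyrimidine synthesis, fell by log2 8.87, with 9 counts left. The leucine tRNA leuW, with 1 count, was 476-fold lower (exact 95% counting interval 85.2 to 18834), and the putrescine oxidase gene puuB, with 3 counts, 277-fold lower (94.5 to 1344). The lysine-cadaverine antiporter gene cadB had 0 counts at 1 ng and was at least 30.9-fold lower. For these 8 genes the adjusted p in edgeR's quasi-likelihood test was between 5.5e-05 and 0.000606, and each was higher or lower in both libraries.

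Several lists had members called higher at 1 ng. Acid resistance genes had 9 of 11 members higher (10 adjusted over the list alone), with gadC up by log2 3.74 and hdeD by 4.31. General stress genes of the sigma factor RpoS had 16 of 26 members higher (18 adjusted over the list alone), such as yjbJ by 3.77 and osmC by 2.44. Sulfate assimilation genes had 9 of 12 higher (9 adjusted over the list alone), with cysP up by 4.57 and cysJ by 3.84. Methionine biosynthesis had 6 of 10 higher (7 over the list alone), with metF up by 3.84 and metK by 2.53. Toxin-antitoxin genes had 9 of 20 higher (10 over the list alone), with yoeB up by 4.01 and relE by 2.97, and heat shock genes also had 9 of 20 (10 higher and 1 lower over the list alone), with ibpA up by 3.05 and clpB by 1.64. Anaerobic metabolism genes split, with 19 of 32 higher, such as the hydrogenase genes hyaC by 5.31 and hyaB by 4.94, and 8 lower (19 and 8 over the list alone). Other stress lists had fewer calls, with 8 higher and 3 lower of 19 oxidative stress genes, 6 higher and 1 lower of 22 SOS genes, and 4 higher and 2 lower of 20 envelope stress genes, the same counts as over each list alone. Of 4 ribosome hibernation genes 3 were higher (3 over the list alone), with sra up by 3.78 and hpf by 1.57.

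Other lists had members called lower at 1 ng. All 9 ATP synthase genes were lower (9 adjusted over the list alone), with log2 changes of -1.86 for atpA and -1.72 for atpD, and 14 of 17 TCA cycle genes were lower (14 over the list alone), with acnB at -3.56 and sdhA at -3.11. Transfer RNAs had 37 of 53 lower and 1 higher (39 and 1 over the list alone), with hisR at -6.07. Pyrimidine biosynthesis had 5 of 6 lower (5 over the list alone), with pyrI at -7.15. Fatty acid degradation had 5 of 8 lower (5 over the list alone), with fadB at -3.78, and DNA replication 7 of 14 (7 lower and 1 higher over the list alone), with nrdA at -2.98. Sugar uptake genes had 25 of 60 lower and 6 higher (26 and 6 over the list alone), with mglB at -3.01. Aerobic respiration had 5 of 19 lower (5 over the list alone), among them the cytochrome bo oxidase genes cyoA and cyoB at -3.41 and -2.95, and camera, a test of each list against the other genes, called the list lower (adjusted p = 0.0127, adjusted p = 0.263 with an estimated correlation). The superoxide dismutase gene sodA was at -4.30 and the glutamine synthetase gene glnA at -2.59. Ribosomal protein genes had no common direction, with 8 higher and 7 lower of 54 (8 and 6 over the list alone) and rplT up by 1.93, and translation factors and RNA polymerase had 1 of 14 lower (0 over the list alone).

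In total 1207 of 3487 genes passed at 1 ng, 606 higher and 601 lower. Camera called 20 lists, among them acid resistance (adjusted p = 5.4e-06), RpoS (7.6e-06), TCA cycle (5.6e-06) and tRNA genes (3.7e-10), and 0 with an estimated correlation (adjusted p = 0.263 for each of these 4 with an estimated correlation). The list tests at 1 ng were added after the data were seen. Total count scaling shifted all 1 ng changes by log2 -0.22 and gave 493 higher and 778 lower. Across genes the 1 ng libraries correlated more closely with the commercial and customized depletion libraries (r = 0.975 and 0.979) than with the 5 ng libraries (0.90).

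**Figure D4:**
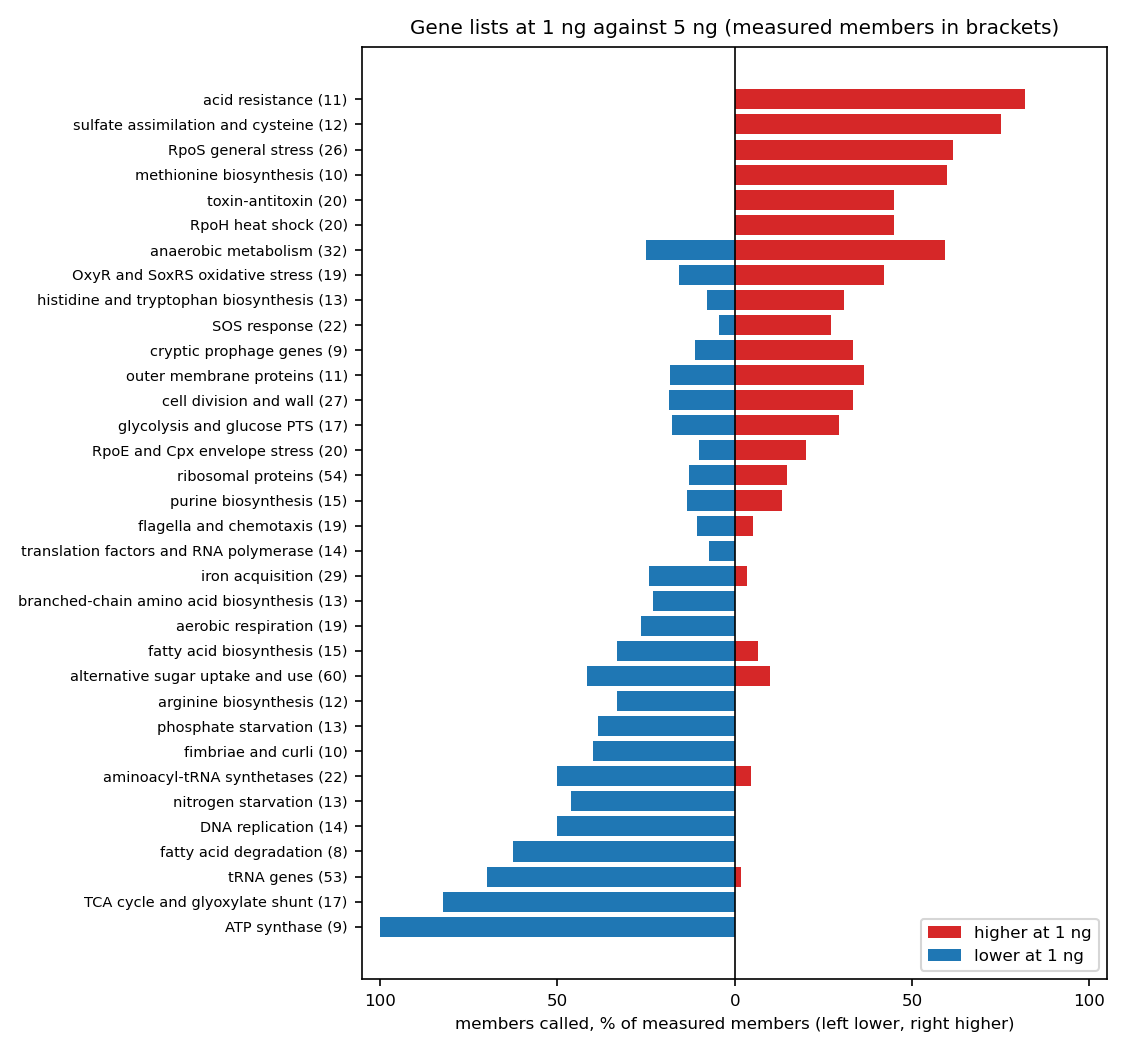
Percent of the measured members of each gene list (number in brackets, lists with at least 8) called higher (red, right) or lower (blue, left) at 1 ng against 5 ng. Acid resistance has 9 of 11 members higher, and ATP synthase has 9 of 9 lower.

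The 100 pg libraries were compared with the same 5 ng libraries as above. hcp, hcr, bssR and the outer membrane protein gene ompW were higher by log2 9.68, 8.27, 6.92 and 6.08, with hcp at 5700 ± 59.7 CPM (SD, n = 2). pyrB, the putrescine genes puuA and puuE, and hisR had 0 counts at 100 pg and were at least 63.8-fold, 17.9-fold, 12.6-fold and 16.1-fold lower, against a floor of 3 counts per library. Acid resistance had 9 of 11 members higher (9 adjusted over the list alone), RpoS genes 12 of 26 (14 higher and 1 lower), and TCA cycle genes 13 of 17 lower (14). Camera called 10 lists, and 0 with an estimated correlation (lowest adjusted p = 0.340 with an estimated correlation). In edgeR's quasi-likelihood test 444 of 3151 genes passed, 213 higher and 231 lower, with adjusted p between 6.5e-05 and 0.00205 for the 8 named genes. Leaving out 1 library changed the genes tested as well, to 2279 or 2292 without 5 ng replicate 1 or 2 and to 3595 or 3586 without 100 pg replicate 1 or 2. Counts of calls from those fits are therefore not set beside the 444. Against the 1 ng libraries edgeR, the only tool run on it, called 0 of 2831 genes, with 124 at an unadjusted p under 0.05.

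At 10 pg few genes could be told apart from 5 ng. hcp was higher by log2 8.45, ytfE, which repairs iron-sulfur clusters, by 4.93 and the acid antiporter gene gadC by 2.48. tnaA had 29 counts over both libraries and was 108-fold lower (exact 95% counting interval 75.4 to 162), and acnB was 44.3-fold lower (24.1 to 92.4). sdhA and maeB, with 3 counts and 1 count, were 53.5-fold (18.3 to 259) and 86.1-fold (15.5 to 3403) lower. TCA cycle genes had 3 of 17 members lower over all genes and 17 of 17 adjusted over the list alone, and acid resistance had 1 of 11 higher and 8 over the list alone. Only 14 of 2984 genes passed, 7 in each direction, with adjusted p between 0.000342 and 0.0420 for the named genes. The count was 766 with DESeq2 and 183 with limma voom. Without 10 pg replicate 1 or 2, 3572 or 3566 genes were tested, so the calls of those fits are not set beside it.

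At 1 pg and 100 fg single genes took much of each library, and the libraries of a pair differed. At 1 pg, ydiQ had 3 and 337 counts, ydfI 5 and 404, barA 757 and 15, and rraA 2 and 198, against 5 ng counts of 3 and 84, 11 and 147, 332 and 183, and 359 and 683. Their log2 changes were 9.80, 9.20, 8.38 and 5.33, and rraA was at -0.25 without 1 pg replicate 2. The nitrate reductase gene narG, rpsN, gabT and pheT had 0 counts and were at least 5.08-fold, 4.18-fold, 4.00-fold and 3.95-fold lower. At 100 fg, yfhL had 396 and 1 counts, amtB 3 and 578, ydfI 11 and 415, and ydiQ 4 and 317. tnaA, mdh, dppA and sucC had 0 counts and were at least 115-fold, 16.1-fold, 11.2-fold and 9.36-fold lower. The 9 genes with at least 50 counts in 100 fg library 1 held 49.6% of its non-rRNA counts, the 18 such genes in library 2 held 70.3%, and barA was in both sets.

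In edgeR's quasi-likelihood test 356 of 2972 genes passed at 1 pg, 90 higher and 266 lower, and 1252 of 2973 at 100 fg, 85 higher and 1167 lower. With the replicate number in the fit 4 genes passed at 1 pg and 1 at 100 fg. Of the genes called lower, 147 at 1 pg and 919 at 100 fg had 0 counts in both libraries. RLE scaling, which moved all genes by log2 1.07 at 1 pg, turned the split to 148 higher and 57 lower, and total count scaling, a shift of 1.08, to 64 and 2. At 100 fg, total count scaling (a shift of 2.12) and limma voom called 0 genes, with 644 and 570 at an unadjusted p under 0.05. Leaving out 1 library also changed which genes passed the low-count filter. Without 5 ng replicate 1 or 2, 244 or 240 genes were tested at 1 pg and 250 or 241 at 100 fg. Without 1 pg replicate 1, 3562 were tested at 1 pg. Counts of calls from these fits are therefore not compared with those above. A simulation at 100 fg in which no gene differed, with 1 common spread per pair for all genes, gave 201 calls, 197 of them lower. At 1 pg the same simulation gave 0 calls. Genes with a spread of their own, such as those above, were not simulated.

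**Figure D5:**
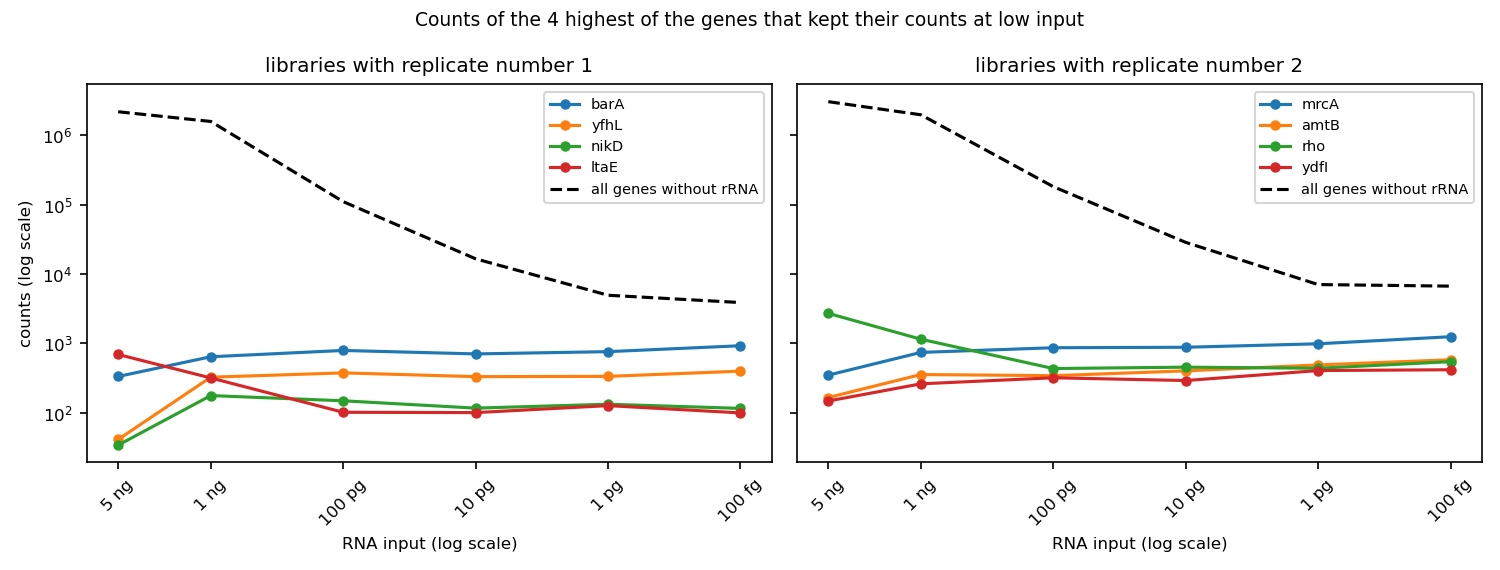
Counts of the 4 genes with the most counts in each 100 fg library across the RNA inputs (both axes log scale), with the non-rRNA total of each library (dashed). From 100 pg to 100 fg the counts of barA stay between 702 and 921 in replicate 1, while the total goes down 28.5-fold.

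The pos and neg libraries were compared as labelled. No gene passed over all genes, with or without the replicate number in the fit, so levels and signs are given as values, and no sign below stands for a gene that passed. Adjusted over the list alone, the fit with the replicate number called 7 of 8 fatty acid degradation, 10 of 60 sugar uptake and 3 of 11 acid resistance genes lower. It called 2 of 13 sulfate assimilation genes higher, and the fit without it called 0 in these lists. The fatty acid oxidation gene fadA was at 777 ± 188 CPM in neg and 528 ± 131 in pos libraries (SD, n = 2), a log2 difference of -0.57 (SE 0.52). The sulfate-binding gene cysP was at 160.2 ± 90.9 and 234.7 ± 103 CPM (0.55, SE 0.42), narG at 15.9 ± 7.43 and 35.9 ± 14.4 (1.16, SE 0.53), and the small RNA micA at 14.4 ± 3.23 and 3.19 ± 0.319 (-2.14, SE 0.92). Within replicate numbers 1 and 2 taken apart, all 8 fatty acid degradation genes had a pos to neg log2 ratio below 0 in both numbers (medians -0.19 and -0.46), and 12 of 13 sulfate assimilation genes had one above 0 in both (0.48 and 0.27). These lists also differed between the numbers, with 8 of 8 lower and 11 of 13 higher in number 2. Their members are not independent, with estimated correlations of 0.995 and 0.931 in the fit without the replicate number.

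The ratio was below 0 in both numbers for 8 of 11 acid resistance genes, 7 of 10 small RNAs, 13 of 26 RpoS genes and 27 of 60 sugar uptake genes. It was above 0 in both for 9 of 14 branched-chain amino acid genes, 8 of 13 histidine and tryptophan genes, 10 of 15 purine genes, 13 of 22 aminoacyl-tRNA synthetase genes and 26 of 54 ribosomal protein genes. Over all 3668 genes the ratio was below 0 in both numbers for 26.0% and above 0 in both for 26.7%, where chance gives 25% each, and r between the ratios of the 2 numbers was 0.0111. The 2 libraries of a label correlated at 0.906 and 0.908 across genes, and libraries of the same number at 0.957 and 0.973.

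Without the replicate number in the fit, edgeR called 0 of 3668 genes, with 3 at an unadjusted p under 0.05. DESeq2 and limma voom, also without it, called 0 as well, with 2 each. These numbers are below what chance gives at that threshold, as the difference between replicate numbers counts as spread in these fits. With the replicate number in the edgeR fit 0 genes were called and 236 were at an unadjusted p under 0.05. Camera called 0 lists, with an adjusted p of 0.0624 for small RNAs, the lowest, and 0.196 for sulfate assimilation (adjusted p = 0.971 for both with an estimated correlation). With the replicate number in the fit it called sulfate assimilation (adjusted p = 0.00429), small RNAs (0.00567), acid resistance (0.00743), fatty acid degradation (0.00743) and pyrimidine biosynthesis (0.0408). Each was at 0.901 once the correlation was estimated too. Leaving out 1 library unbalances the replicate numbers, between which 1469 of 3668 genes differed. Lists called in such fits cannot be read as pos against neg. At the coefficient of variation of these libraries, 0.583, simulated 4-fold changes were recovered in 0% of genes by the edgeR fit that leaves the replicate number out. With the replicate number in the fit the coefficient was 0.155. In a simulation with a difference between the numbers, that fit recovered 75% of 4-fold and 51% of 2-fold changes.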

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

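Few counts and the spread between the 2 libraries of a pair both limit what can be seen at 10 pg and below, without a test of which limits more, and single libraries without replicates limit the comparisons of protocols. The 39 results for named genes, each under several settings, gave 491 values, of which 397 kept their direction and side of the threshold, 88 were weaker and 6 reversed. With 1 ng as the reference, log2 changes reversed to -0.0304 for bssR and -0.0842 for ompW at 100 pg, and to -0.93 for hcp, -0.71 for ytfE and -0.80 for gadC at 10 pg. Without 1 pg replicate 2, rraA reversed to -0.25, and the values with 1 library left out ranged from -0.25 to 6.10. Apart from settings that remove libraries or genes, the cause was not tested.

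With all 12 input libraries in one fit, 73 genes were called at 1 ng (1207 in the report), 77 at 100 pg (444), 320 at 10 pg (14) and 411 at 100 fg (1252). That fit tested 1637 genes, against 3487 at 1 ng and 3151 at 100 pg in the report, so the set of genes changed along with the fit. At 10 pg the count was 41 with RLE, 75 with no low-count filter, 766 with DESeq2, 183 with voom and 51 with rRNA kept. At 1 pg (356) it was 205 with RLE, 595 with no filter, 570 with rRNA kept and 66 with total count scaling, and at 100 fg it was 545 with RLE, and 0 with voom and with total count scaling. With 1 ng as the reference 0 were called at 100 pg, 0 at 10 pg and 179 at 1 pg. Leaving out 1 library in turn gave 883 to 1441 genes at 1 ng, 211 to 1180 at 100 pg, 16 to 1188 at 10 pg, 0 to 623 at 1 pg and 0 to 1392 at 100 fg, where the lone library of a group is assumed to vary like the others. Each such fit also tested a different number of genes. At 1 pg 244 or 240 were tested without 5 ng replicate 1 or 2, against 2972 in the report. At 100 pg 3595 or 3586 were tested without 100 pg replicate 1 or 2, against 3151. The ranges are therefore no measure of how far the calls rest on 1 library. Higher and lower calls were 493 and 778 at 1 ng with total count scaling (606 and 601 in the report). At 10 pg (7 and 7) they were 26 and 15 with RLE and 16 and 4 with total count scaling. They were 232 and 534 with DESeq2, 5 and 178 with voom, 42 and 278 in the fit of all 12, and 21 and 69 with the replicate block. At 1 pg (90 and 266) they were 148 and 57 with RLE, 64 and 2 with total count scaling, 261 and 212 with DESeq2 and 24 and 391 with voom.

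Same-numbered libraries share only a number in the labels. Their deviations correlated at 0.445 for 5 ng and 1 ng, 0.187, 0.0925, 0.107 and 0.0431 for the lower inputs in turn, and 0.890 for pos and neg, over genes with a mean of 50 counts in the 4 libraries. Over genes with a mean of 20 counts in each pair the values were 0.417, 0.410, 0.385, 0.452 and 0.309, on 2674, 1023, 230, 32 and 28 genes, and 0.843 for pos and neg. With the replicate block 1773, 525, 90, 4 and 1 genes were called from 1 ng down to 100 fg, and 0 for pos against neg, with 236 at an unadjusted p under 0.05. For pos against neg, simulated 4-fold changes were recovered in 75% of genes and 2-fold changes in 51% with the block, over 3668 genes, and in 0% without it. Lists called for pos against neg went from 0 to 5 with the block, and to 0 with the block and an estimated correlation (adjusted p = 0.901 for each of the 5). Adjusted over the list alone, the block called 7 of 8 fatty acid degradation, 10 of 60 sugar uptake, 3 of 11 acid resistance, 2 of 10 small RNA, 2 of 11 outer membrane protein and 1 of 4 ribosome hibernation genes lower in pos, and 2 of 13 histidine and tryptophan, 2 of 13 sulfate assimilation and 1 of 14 nitrogen starvation genes higher, and the fit without it called 0 in every list. With the block at 1 ng, over the list alone, 14 of 19 aerobic respiration genes were called lower (5 in the report), 26 of 54 ribosomal protein genes higher and 13 lower (8 and 6), 3 of 14 translation factor and RNA polymerase genes in each direction (0), 7 of 20 envelope stress genes higher and 4 lower (4 and 2), and 8 of 22 SOS genes higher and 3 lower (6 and 1). The 20 lists called at 1 ng went to 0 with an estimated correlation, and to 0 with the replicate block and estimated correlation.

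Detected genes from 5 ng down were 3799, 3513.5, 2040, 825 and 198 unthinned to 1 pg. They were 2072, 1949, 1838, 1192, 800.0 and 479.6 with a minimum count of 1, and 353.9, 330.9, 318.2, 212.7, 68.5 and 46.3 with a minimum of 10. Thinned to the smallest total without rRNA they were 179, 182, 184, 192 and 129 down to 1 pg. Replicate correlation was 0.962, 0.908, 0.719 and 0.484 from 5 ng to 10 pg with a pseudocount of 0.1, and 0.987, 0.976, 0.850 and 0.561 with 10. Over genes with at least 10 counts in one library it was 0.973, 0.927, 0.562, -0.00613, -0.500 and -0.511, and with rRNA kept it was 0.536, 0.345 and 0.286 from 10 pg down. Correlation with 5 ng was 0.889, 0.804, 0.602 and 0.420 from 1 ng to 1 pg with a pseudocount of 0.1. With 10 it was 0.891 at 1 ng, 0.690 at 10 pg and 0.466 at 1 pg. Over genes with at least 10 counts it was 0.845 at 1 ng, 0.778 at 100 pg, 0.401 at 1 pg and 0.200 at 100 fg, and with 1 ng as the reference 0.915, 0.711 and 0.484 from 100 pg to 1 pg. Leaving out 1 library in turn it was 0.887 to 0.897 at 1 ng, 0.786 to 0.839 at 100 pg, 0.555 to 0.641 at 10 pg, 0.369 to 0.440 at 1 pg and 0.187 to 0.252 at 100 fg.

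At least 2-fold apart after the depletion methods were 246 genes with a minimum count of 10 and 58 with 200, and r was 0.973 with a pseudocount of 0.1 and 0.986 with 10. For miniBac-seq against TruSeq the counts were 1117 and 441, and r was 0.919, 0.958 and, without tRNA and other non-coding genes, 0.953. For the RT primers limma voom made 376 calls (247 in the report), and the coefficient of variation was 0.357 with no low-count filter (0.278).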

Other observations

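All tests weighed in this section were chosen after the result was seen. Sets of libraries differed in marker genes of respiration and stress. hcp was at 6037 and 5874 CPM in the commercial and customized depletion libraries and at 1731 ± 152 CPM in the RT primer libraries (SD, n = 24), but at 1.89 and 4.08 CPM in the miniBac-seq and TruSeq libraries. tnaA was at 7202 ± 815 CPM with the RT primers and at 14.2 and 17.7 CPM with miniBac-seq and TruSeq. gadB was at 8.63 CPM on average with the RT primers, against 28074 and 30686 CPM after depletion. The anaerobic threonine and nitrate genes tdcE and narG were at 10156 ± 1040 and 8566 ± 1094 CPM with the RT primers, and narG was at 8.50 and 23.5 CPM with miniBac-seq and TruSeq. The porin gene ompF was at 6684 ± 3279 CPM in neg and 4536 CPM in miniBac-seq libraries, and at 204 CPM after commercial depletion.

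Among the pos and neg libraries, those numbered 2 differed from those numbered 1. All 11 acid resistance genes were lower in number 2 (11 adjusted over the list alone, median log2 -2.15, adjusted p = 8.1e-06 in camera, adjusted p = 0.561 with an estimated correlation), with gadB at -2.15 and hdeB at -2.47. All 8 fatty acid degradation genes, 21 of 26 RpoS genes, 12 of 14 nitrogen starvation genes and 38 of 60 sugar uptake genes were also lower (8, 21, 12 and 38 adjusted over the list alone), with malE at -2.09 and lamB at -2.45. Sulfate assimilation had 11 of 13 members higher (12 over the list alone) and cold shock 6 of 8 (6 over the list alone), with cspG at 4.51 and cspB at 2.28. ydeT had 0 counts in number 1 and 363 in number 2, at least 90.7-fold higher. edgeR's quasi-likelihood test called 1469 of 3668 genes between the numbers, 737 higher and 732 lower in number 2. The labels give these 4 libraries the same RT primer, and the differences between numbers correlated at most at 0.243 in neg and 0.231 in pos with any difference between 2 RT primers.

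In the first pattern, background genes at low input, genes such as barA in library 1 kept nearly constant counts from 100 pg to 100 fg, with median ratios of highest to lowest counts of 1.35 and 1.73, while totals went down 28.5-fold and 27.2-fold. Priming that depends on the RT primer stays open, since 9 of 27 such genes over both numbers were highest with the primer of the same number, where chance gives 1.12, yet 7 ranked below 12 of 24, and barA ranked 6 and 11. Against carry-over of reads from the 1 ng library, these genes held at most 0.508% of the counts at 1 ng and 49.6% and 70.3% at 100 fg. Against reads that every library shares, 25 genes were in the set of 1 library and 1 in both. The other 100 fg library held a median of 1.17% of the CPM of the 25 genes. That share is kept low by the choice of genes with under 50 counts in the other library, so it adds little. For barA, in both sets with 921 and 109 counts, the CPM in library 2 was 6.86% of that in library 1. This is 1 ratio for 1 gene and cannot decide on shared reads, which stay open for it. With barA the genes of library 2 held 25.8% of the counts of library 1, against 1.83% the other way. No biological explanation was tested, and which primers the input libraries carried is not given in the sources used here.

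Replicate differences shared across inputs and depletion kits form the second pattern. The difference between libraries 2 and 1 correlated best with that between RT primers 2 and 1 of all ordered primer pairs in 4 of 4 library pairs, with r of 0.637 at 5 ng, 0.575 at 1 ng, 0.429 at 100 pg and 0.610 for customized over commercial depletion, so RT primers 1 and 2 may lie behind it. Of the 96 genes 2-fold apart between depletion methods, 35 were measured there, and 14 were 2-fold apart in the same direction, against a median of 2 and a highest value of 14 over all primer pairs. A difference in depth did not remove it (r = 0.602 after thinning to 1114984 counts). Different RNA behind each number stays open, since r of the 5 ng and 1 ng differences went from 0.636 to 0.410 after regression on the primer difference, and noise in the primer libraries leaves part of it in either case.

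In the third pattern, expression at 1 ng against 5 ng, loss of transcripts that grows as the input falls would move genes further at 100 pg, but the 225 genes called lower with at least 10 counts expected there from their 1 ng level, at a median log2 change of -1.36, moved 0.00639 further down (bootstrap 95% interval -0.0600 to 0.0716), and the 442 called higher, at 1.38, moved by -0.0690 (-0.110 to -0.0509). For the other 376 genes called lower, with a median of 2.41 counts expected and 83 at 0 counts at 100 pg, loss of single genes stays open. All 37 tRNA genes called were among them, and in sum these held 3199 CPM at 5 ng, 356 at 1 ng and 367 at 100 pg. Genes called for a low level at 1 ng may rise at 100 pg through that choice alone, so these sums are a weak test. All tRNA genes, without that choice, held a mean of 0.0570% of non-rRNA counts at 1 ng and 0.0686% at 100 pg. For the tRNA genes as a set these values argue against further loss, but not for single tRNA genes. The tRNA list medians of -2.64 at 1 ng and -3.56 at 100 pg rest on 53 and 48 measured genes. A difference in depth would lower the number of calls, and 1175 genes were still called at 1 depth. Another RNA sample behind the 5 ng libraries may account for the profile, since 1 ng correlated with the depletion libraries at 0.975 or more and with 5 ng at 0.90. Whether that sample came from another culture or another state of growth stays open.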
